A study of Homo sapiens with 8 samples.

How the data were processed

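Chromatin immunoprecipitation followed by hybridization to custom DNA arrays (ChIP-chip) was carried out in 2 human cell lines, MCF7, a breast carcinoma line, and U251, a glioblastoma line. Per the labels, MCF7 cells are non-migratory and U251 cells are migratory. Cells were crosslinked for 10 min with 1% formaldehyde, and chromatin was cut with micrococcal nuclease to about 80% mononucleosomes and 20% dinucleosomes, per the labels' protocols. Precipitations used 10 μg of antibody on 100 μg of chromatin, and 10 ng of the recovered DNA was amplified by a whole-genome method before labelling. On each array the Cy5 channel held the immunoprecipitated DNA (IP) of 1 antibody and the Cy3 channel held whole-cell extract DNA of the same line (input). No dye swap was among the arrays. Samples were grouped by the line and antibody in their titles, which gave 8 groups (4 antibodies in 2 lines) of 1 array each. The labels state that precipitations were made in triplicate but not whether these were pooled, and the protocol text names H3ac, H3K4me2 and H3K27me3 antibodies but gives no detail for POL2. The IgG and no-antibody controls that the protocol mentions were not analysed here.

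Per the file headers, the scanner files hold spot intensity values from Agilent Feature Extraction 9.5.3.1, with probe positions on hg18 (NCBI build 36). The submitters' processing notes name version 10.5 of the same program. The processed intensity of each channel was, per the file headers, corrected for background with a spatial detrend surface, corrected by multiplicative detrending and scaled by 1 linear dye factor per channel, with surrogate values for spots at background. The local background and mean intensity columns, deposited beside them, were used only for the normexp alternative. The log10 ratio column, computed from the processed channels per the file headers, was used only as a check of direction and matched the recomputed ratio in 97.8% to 99.5% of spots. The authors' deposited value table holds 6920 values per array whose spread matches a log2 ratio. Its medians lay between 0.42 and 1.41, so its centring stays unknown, and its row numbers matched no probe column of the scanner files. Its direction could not be checked probe by probe either, and only its column medians were used.

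All 8 arrays lay on 1 slide and came from 1 scan, with the MCF7 arrays in slide column 1 and the U251 arrays in slide column 2, so that slide column and cell line cannot be told apart. The arrays carried 6920 probes for 547 gene names, each probe in 1 to 51 spots and most (4851) in 2 spots. The labels state 3 to 10 spots per probe and 486 genes. Of the gene names, 498 matched a current symbol, 41 matched a synonym and 8 matched nothing in the reference gene table, and names are given here as the files give them. The input was well above background in 98.2% to 99.3% of spots and the IP channel in 95.5% to 99.3% per array. The pooled SD of the log2 ratio over spots of 1 probe was 0.07 to 0.11. Flagged outlier spots and control spots were left out, and saturated spots were kept. A total of 144 probes were left out. On at least 1 array their input was well above background in fewer than 50% of unflagged spots, or they had no unflagged spot. This left 6776 probes and 534 genes with at least 3 probes (median 10, highest 159).

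The log2 ratio of processed IP over processed input was averaged over the spots of a probe and centred on each array's median. No loess or quantile step was used in the main values, since many probes on such an array carry signal. The difference of a gene is the mean over its probes of U251 minus MCF7, given with the SD over probes. With 1 array per line and antibody there is no replicate check and no p-value for these differences. The SD over probes describes the region and not the error between cultures. A gene was called higher or lower by size alone, with a mean difference of at least 1 on the log2 scale (2-fold), at least 3 probes and at least 80% of its probes with the same sign. Gene lists of at least 3 measured genes were described by their median and its percentile among 10000 random lists of the same size, matched on the quartile of the mean log2 ratio. A list was taken to stand apart below the percentile 2.5 or above 97.5. This rule was applied to each list and antibody without correction for their number, so some medians would stand apart by chance. Relations between antibodies were described by Pearson's r and Spearman's rho across genes, which are not independent replicates, with an interval from 1000 bootstrap draws of genes. Input DNA was compared between the lines with limma 3.58.1 (lmFit and eBayes) on gene means of log2 Cy3 intensity centred per array, 4 input channels against 4. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of at least 0.5. The labels do not say whether the 4 inputs of a line are separate preparations, so these p-values measure the spread between hybridizations, which may be technical.

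The lists, the size rule and the rule for named genes were fixed before the data were examined. The named genes are, per antibody, the 8 largest called differences each way, a fixed set of 19 genes of invasion, adhesion and housekeeping (those with at least 3 probes, which leaves out VIM and ESR1), the 3 largest members of each list, the 10 genes with the largest opposite change of H3K27me3 and an active mark, and the 8 largest input differences each way. Lists covered matrix metalloproteinases, their inhibitors, ADAM and ADAMTS proteases, collagens, laminins and other matrix glycoproteins, integrins with CD44, cadherins and catenins, the plasminogen system, cathepsins with furin, growth factors of angiogenesis, tumour suppressor and cell cycle genes, chromatin modifiers, developmental polycomb targets, housekeeping genes, and markers of epithelial, luminal breast, mesenchymal, glial, neuronal and blood cells. Chemokine and interleukin lists were added after the values were seen.

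Alternatives were normexp background correction (offset 50), loess within each array, quantile normalization between the 2 arrays of an antibody, the median over probes, the 3 highest probes, no filter on dim probes, a filter on both channels, odd-ranked or even-ranked probes alone, size thresholds of 0.5 and 1.5, no minimum share of probes, 250 bp bins and, for the input, the antibody as a block and leaving out each array in turn. Added after seeing the data were a lowess correction of each array for probe GC content, the use of probes within 1000 bp of a transcript start, and the removal of the input difference. Normexp, loess, quantile normalization and the GC correction are called the 4 scaling alternatives. Tested on simulated data on the 534 genes, with 200 changed, the size rule recovered 99% of genes shifted by 1.5 and 100% of those shifted by 2 on the H3acetyl arrays, with 0 false calls. These simulated arrays held the scatter between probes but no gene-level error between hybridizations or cultures. The 0 false calls therefore do not measure that error. The limma step recovered 98% of input shifts of 0.7 and 100% of shifts of 1. Work was done in R 4.3.3 with the data.table package (version 1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.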

Results

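The arrays measured, at promoters and some gene bodies of 534 genes, how much DNA was recovered with antibodies against H3K27me3 (a mark of Polycomb-repressed chromatin), acetylated histone H3 and H3K4me2 (both found at active or accessible promoters), and RNA polymerase II (POL2). MCF7 is a breast carcinoma line with epithelial traits and U251 is a glioblastoma line. Per the labels the pair contrasts a non-migratory with a migratory line, and the series title names epigenetic control of pro-invasive genes as the subject. Each line and antibody had 1 array, which limits the precision of every value below, and the differences have no replicate check. Median input intensity was 487 (MCF7) and 505 (U251) on the H3K27me3 arrays and 615 to 733 on the other 6 arrays. All values are log2 ratios of IP over input relative to the array's median, and all differences are U251 minus MCF7 with the SD over the gene's probes. Genes named outside the rule that was fixed before the data were examined, such as ID1, ID3, PARD6B, TP53, GJA1 and the examples from overlaps of calls, were chosen after their values were seen.

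Within each line, H3acetyl, H3K4me2 and POL2 marked largely the same genes, and H3K27me3 marked mostly others. Gene means of at least 1 were reached by 106 genes for H3acetyl, 93 for H3K4me2, 34 for POL2 and 40 for H3K27me3 in MCF7, and by 173, 163, 80 and 46 genes in U251. The highest POL2 means belonged to ID1 in MCF7 (2.29) and ID3 in U251 (2.70), which encode inhibitors of DNA binding proteins, and the highest H3acetyl means to PARD6B in MCF7 (2.58), a cell polarity gene, and TP53 in U251 (2.89). All 3 active marks reached 1 at 30 genes in MCF7 and 68 in U251, against 1.18 and 7.91 for independent lists. No gene reached 1 for both H3K27me3 and H3acetyl in either line (7.94 and 14.9 for independent lists). H3K27me3 with H3K4me2 reached 1 at 7 genes in MCF7 (ADAMTS1, ASCL1, BDNF, COL12A1, GJB2, LAMB1 and SSTR2), close to the 6.97 for independent lists, and at POU3F3 alone in U251, against 14.04. Across genes, H3K27me3 correlated with H3acetyl at r = -0.446 (rho = -0.458) in MCF7 and r = -0.630 (rho = -0.640) in U251. H3acetyl correlated with POL2 at r = 0.902 (rho = 0.904) and r = 0.923 (rho = 0.930). Between the lines, the same antibody correlated at r = 0.334 for H3K27me3, 0.632 for H3acetyl, 0.757 for H3K4me2 and 0.640 for POL2.

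Around transcript starts H3acetyl and H3K4me2 formed a pair of shoulders with a dip just upstream of the start. In 500 bp bins, H3acetyl was highest 500 to 1000 bp downstream of the start in MCF7 (0.51 ± 1.18, SD over 665 probes) and in U251 (0.73 ± 1.38). H3K4me2 was highest at 500 to 1000 bp in MCF7 (0.39 ± 1.23) and at 1000 to 1500 bp in U251 (0.59 ± 1.24, 638 probes). POL2 was highest in the first 500 bp in MCF7 (0.33 ± 0.80, 677 probes) and at 500 to 1000 bp in U251 (0.42 ± 0.92). In the bin starting 2000 bp downstream, the H3K4me2 mean was 0.45 in U251 and -0.0058 in MCF7, and the H3acetyl mean was 0.50 and 0.083. The H3acetyl mean of the last 500 bp before the start was 0.19 in MCF7 and 0.28 in U251. The H3K27me3 means of bins with at least 444 probes stayed between -0.13 and 0.13 in both lines, and in every bin the SD over probes was larger than the mean.

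**Figure D1:**
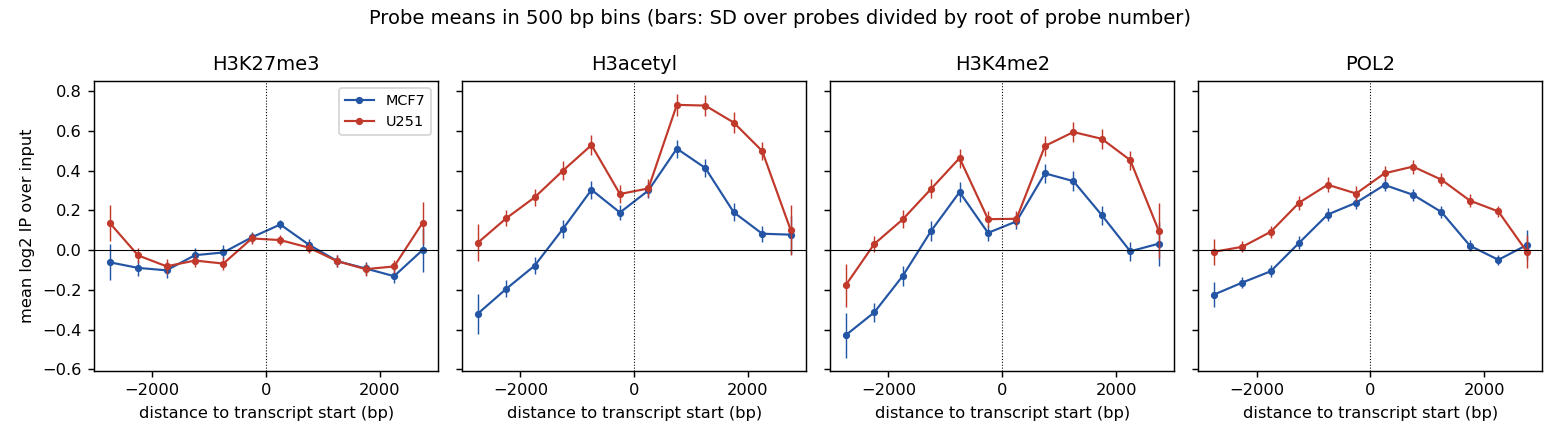
Mean log2 ratio of IP over input (y axis) of probes in 500 bp bins by distance to the nearest listed transcript start in bp (x axis), for MCF7 in blue and U251 in red, 1 array each, with bars of the SD over probes divided by the root of the probe number. H3acetyl peaks at 0.51 in MCF7 and 0.73 in U251, both 500 to 1000 bp downstream.

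H3K27me3 differed in both directions between the lines. The largest lower differences in U251 were at LAMB1, a laminin chain, with -2.43 ± 0.98 (10 probes), TNC, the matrix glycoprotein tenascin C, with -2.43 ± 0.82, COL8A1 with -2.34 ± 0.73, SGCE, a sarcoglycan, with -2.31 ± 0.58 (4 probes) and COL12A1 with -1.84 ± 0.72. The transcription factor MEF2C (-1.84 ± 0.93), the neurotrophin BDNF (-1.83 ± 0.69) and the collagenase MMP1 (-1.80 ± 0.67 over 32 probes) followed. Higher in U251 were the B cell factor PAX5 (1.89 ± 1.02), the T cell receptor component CD3G (1.81 ± 0.48), the chemokine receptor IL8RA, now CXCR1 (1.76 ± 0.35), the tyrosine kinase SYK (1.71 ± 0.83), the chemokines CCL19 (1.61 ± 0.42) and CCL14 (1.59 ± 0.65), the receptor CCR8 (1.58 ± 0.65) and LECT1 (1.57 ± 0.84), a cartilage protein now named CNMD. In all, 45 genes were called higher and 49 lower of 534. The probes of LAMB1 span chromosome 7, 107428627 to 107433031, those of TNC chromosome 9, 116917838 to 116922765, those of MMP1 chromosome 11, 102171610 to 102181938, and those of PAX5 chromosome 9, 37022174 to 37026825 (all hg18). At TNC, 5 probes lie in the promoter and 5 inside the gene, and all 10 went the same way. Normexp background correction lowered the count of lower genes to 30, and with probes within 1000 bp of a start LECT1 was at 0.92 and not called.

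H3acetyl was higher in U251 at far more genes than it was lower. The largest differences were at the fibrillar collagen gene COL11A1 (3.61 ± 0.61, from -0.94 in MCF7 to 2.67 in U251), TNC (3.53 ± 0.89), SGCE (3.45 ± 0.61) and the basement membrane collagen gene COL4A2 (2.99 ± 1.51). The histone deacetylase gene HDAC9 (2.92 ± 0.91), SPP1, which encodes osteopontin (2.88 ± 0.98), the norrin gene NDP (2.84 ± 0.95) and the cadherin gene CDH6 (2.67 ± 0.86) came next. The lowest values in the 4 scaling alternatives were 1.98, 2.16, 1.54 and 1.56 for COL11A1, TNC, SGCE and COL4A2. For HDAC9, SPP1, NDP and CDH6 they were 1.74, 1.34, 1.33 and 1.54. Lower in U251 were MTSS1 (-1.90 ± 1.02), a membrane-actin scaffold, SYK (-1.86 ± 1.03), the E-cadherin gene CDH1 (-1.68 ± 1.02), the chemokine CXCL12 (-1.52 ± 0.86), the transcription factor ASCL2 (-1.51 ± 1.07), SHH (-1.44 ± 0.63), the cytokine MIF (-1.40 ± 0.91) and the receptor IL10RA (-1.26 ± 0.86). The size rule, with no replicates and so no p-value, called 74 genes higher and 9 lower. COL11A1 probes span chromosome 1, 103344453 to 103349059, and CDH1 probes chromosome 16, 67326220 to 67330073. The IL10RA call held in 2 of the 4 scaling alternatives (lowest size -0.55). The split depended on scaling: quantile normalization gave 52 higher and 20 lower, the GC correction 40 and 10, and normexp background correction 20 and 23. Across genes the H3acetyl difference fell with probe GC content (r = -0.511, rho = -0.608), and so did those of H3K4me2 (r = -0.466) and POL2 (r = -0.445), while that of H3K27me3 rose slightly (r = 0.134).

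H3K4me2 was higher in U251 mostly at genes that were also higher for H3acetyl. NDP (2.92 ± 0.84), the interleukin gene IL1A (2.80 ± 0.64), SPP1 (2.65 ± 1.14), COL4A2 (2.63 ± 1.08), COL4A1 (2.45 ± 0.77), COL11A1 (2.43 ± 1.18), TNC (2.37 ± 0.92) and the vascular adhesion molecule VCAM1 (2.30 ± 1.24) were highest in U251. SYK (-2.03 ± 1.04), IL10RA (-1.83 ± 1.12), MTSS1 (-1.54 ± 0.59), MIF (-1.40 ± 0.77), the endoderm factor FOXA2 (-1.35 ± 0.67), the dopamine receptor DRD1 (-1.31 ± 0.55), the neurotrophic factor ARTN (-1.16 ± 0.58) and the metalloproteinase inhibitor TIMP3 (-1.05 ± 0.65 over 44 probes) were lower. CDH1 was lower as well (-1.03 ± 0.55). The counts were 49 higher and 10 lower, and 39 of the 49 were also called higher for H3acetyl (6.79 for independent lists). Quantile normalization gave 38 higher and 18 lower, the GC correction 31 and 15, and loess 27 and 8.

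POL2 was higher in U251 at 34 genes and lower at 4. COL11A1 (2.47 ± 0.61), TNC (2.16 ± 0.76), SGCE (2.01 ± 0.90), COL4A2 (1.91 ± 0.61), TGFBI, a matrix protein induced by TGF-beta (1.90 ± 0.86), the monocyte attractant CCL2 (1.89 ± 1.24), NDP (1.83 ± 0.85) and the matricellular factor CTGF (1.78 ± 0.68) led. The 4 lower genes were CDH1 (-1.32 ± 0.78), ASCL2 (-1.06 ± 0.71), the interleukin gene IL17C (-1.05 ± 0.77) and MIF (-1.02 ± 0.56), and the median over probes called none of them. CDH1 kept this call in all 4 scaling alternatives, MIF and ASCL2 in 1 each. Of the 34 higher genes, 33 were also called higher for H3acetyl. All 3 active antibodies called 17 genes higher, among them COL4A1, COL8A1, GJA1, MEF2C, MET, NRG1, PTN and SPARC, and 2 lower, CDH1 and MIF. The POL2 call of PTN held in 0 of the 4 scaling alternatives and that of MET in 3. Relative to all genes these differences sit on a shifted scale: the median difference of all genes was 0.17 for H3acetyl, 0.14 for H3K4me2 and 0.090 for POL2, and it became -0.090, -0.084 and -0.041 after quantile normalization and -0.10, -0.076 and -0.033 after the GC correction.

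**Figure D2:**
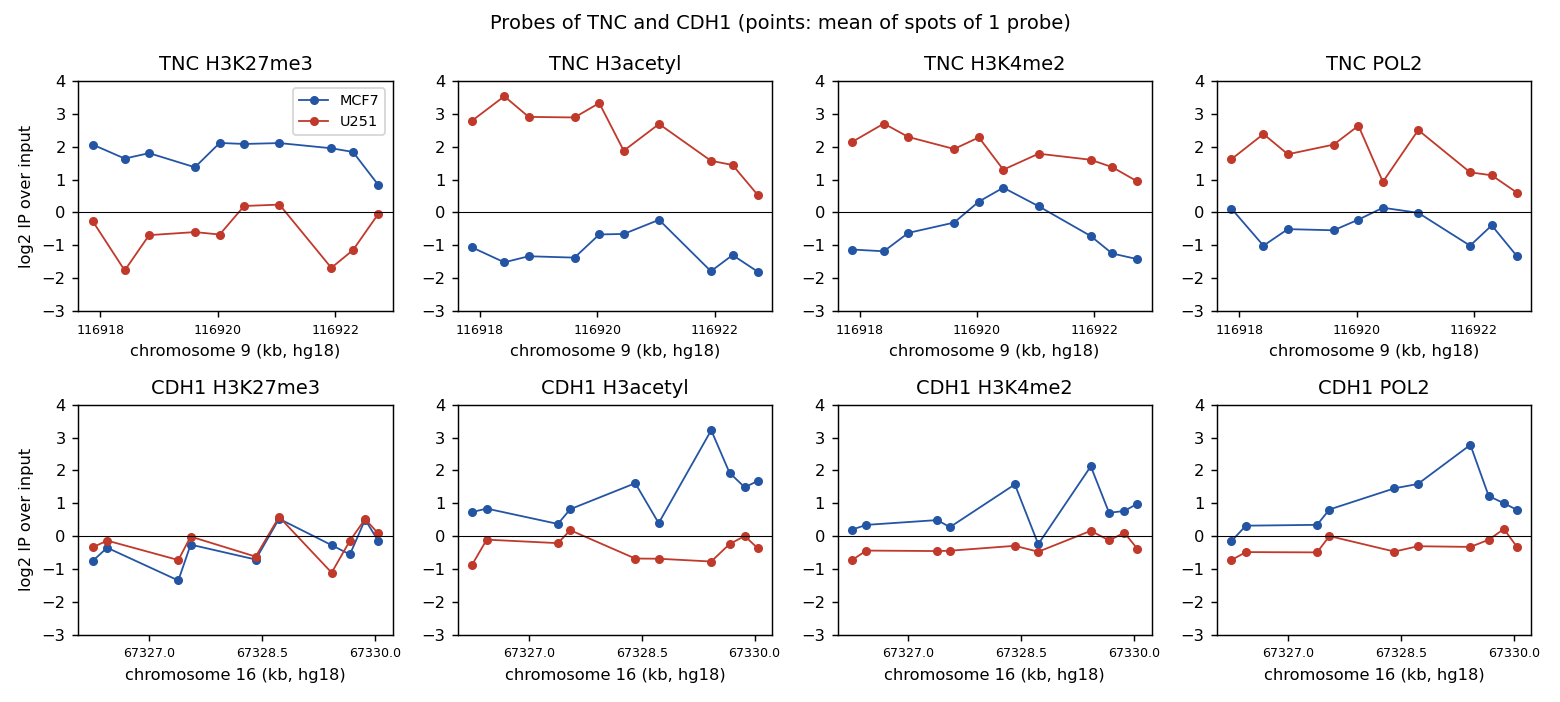
Log2 ratio of IP over input (y axis) at each probe of TNC (upper row) and CDH1 (lower row) against hg18 position in kb (x axis), MCF7 in blue and U251 in red, 1 panel per antibody. At TNC the gene mean of H3K27me3 is 1.78 in MCF7 and -0.64 in U251 and that of H3acetyl is -1.17 and 2.36, while at CDH1 H3acetyl is 1.31 and -0.38.

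The repressive and active marks changed in opposite directions at a set of genes larger than independent lists would share. A total of 37 genes were lower in U251 for H3K27me3 and higher for H3acetyl or H3K4me2, against 7.71 for independent lists. The widest gaps were at TNC, SGCE, COL8A1, COL11A1, NDP, the neuregulin gene NRG1, HDAC9, the growth factor PTN, CDH6 and COL4A2. NRG1, for example, was at -1.70 for H3K27me3, 2.66 for H3acetyl, 1.38 for H3K4me2 and 1.48 for POL2. Of the 49 genes lower for H3K27me3, 22 were higher for POL2 (3.12 for independent lists), among them BDNF, COL12A1, CTGF, GJA1, MEF2C and CCL2, which was not called for H3acetyl. The reverse, higher H3K27me3 with a lower active mark, was found at 2 genes, SYK and MTSS1 (1.10 for independent lists). Normexp background correction gave 12 genes of the first kind and loess gave 20, and COL11A1 kept its H3K27me3 call in 1 of the 4 scaling alternatives and COL4A2 in 2. Across genes, the H3K27me3 difference correlated with that of H3acetyl at r = -0.580 (rho = -0.466), of H3K4me2 at -0.366 (-0.275) and of POL2 at -0.499 (-0.404). The H3acetyl and POL2 differences correlated at r = 0.904 (rho = 0.895). An input shared by the antibodies of a line would add covariance of the positive sign only. The observed covariance was 0.355 for H3acetyl with POL2 and -0.313 for H3K27me3 with H3acetyl. Unchanged lines simulated with the measured spread of the input gave r = 0.498 and a covariance of 0.0445 for every pair of antibodies. Each array had its own input channel, so the spread between channels does not measure what the antibodies share. The simulation therefore cannot say how much of the positive covariance a shared input adds.

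**Figure D3:**
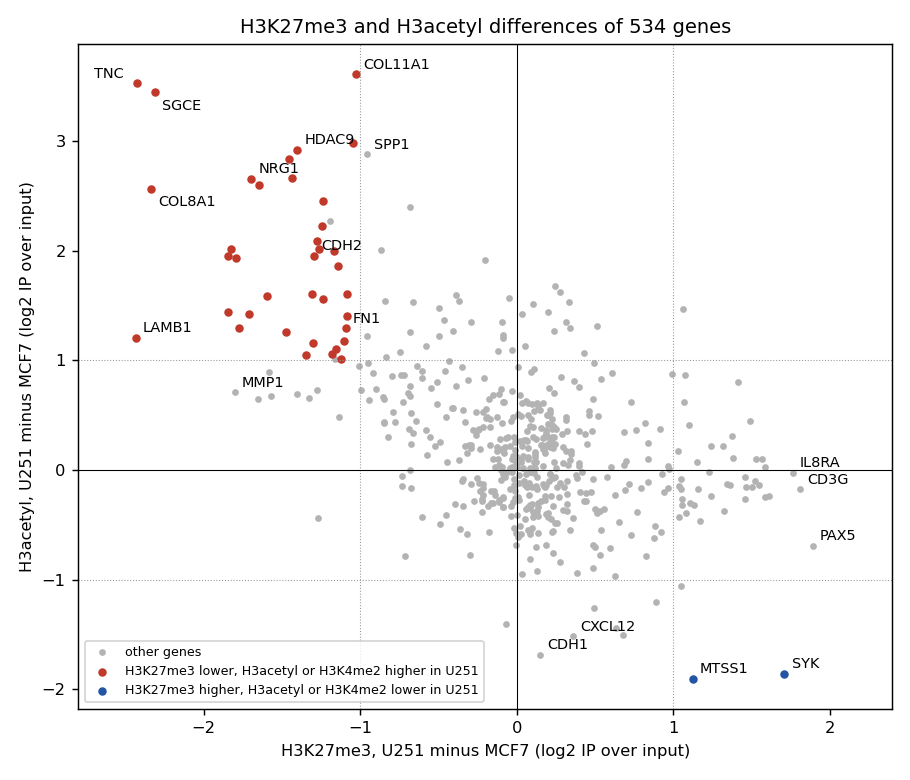
H3K27me3 difference (x axis) against H3acetyl difference (y axis), both U251 minus MCF7 in log2 IP over input, for 534 genes from 1 array per line and antibody, with dotted lines at the size threshold of 1. The 37 red genes were called lower for H3K27me3 and higher for H3acetyl or H3K4me2, and the 2 blue genes, SYK and MTSS1, the reverse.

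Of the 37 genes, 10 were from the collagen and glycoprotein lists, an overlap that was not tested. Of 17 laminins and matrix glycoproteins, 9 were higher and 0 lower for H3acetyl, including FN1, the fibronectin gene (1.29 ± 0.67), SPARC (2.01) and VCAN (1.93), with a list median of 1.21 (percentile 99.98). For POL2, 5 were higher (median 0.70, percentile 99.995), for H3K4me2 5 were higher (0.43, 98.4), and for H3K27me3 5 were lower and ACAN alone was higher (1.36) (median -0.22, percentile 1.36). After the GC correction the H3K27me3 and H3K4me2 medians no longer stood apart (percentiles 6.33 and 96.7), and each stood apart in 7 of 12 alternatives. The H3acetyl median stood apart in 12, with a lowest value of 0.44, and that of POL2 in 11, with a lowest value of 0.21. Of 18 collagens, 8 were higher for H3acetyl (median 0.51, percentile 91.5), 5 for H3K4me2 (0.25, 84.7) and 5 for POL2 (0.43, 99.6), 5 were lower for H3K27me3 and COL2A1 was higher (1.05), with a median of -0.25 (percentile 2.63). COL1A1 was not called for any antibody (H3acetyl 0.52 ± 0.57), but with probes within 1000 bp of a start it was lower for H3K27me3 (-1.10) and higher for POL2 (1.08). COL4A1 and COL4A2, neighbours on chromosome 13 (probes from 109755155 to 109759810), went together for all 4 antibodies. Their probes share this single short stretch, so the pair may report a single region, although each is counted as a gene.

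All 4 measured mesenchymal markers, CDH2, FN1, TGFBI and SPARC, were higher for H3acetyl (median 1.78, percentile 99.5), 3 for POL2 (1.26, 99.6) and SPARC for H3K4me2 (0.74, 98.1), and 3 were lower for H3K27me3 (-1.18, 0.62). FN1 and SPARC also belong to the glycoprotein list. Of 12 alternatives, the list stood apart in 9 for H3acetyl, 12 for POL2, 11 for H3K27me3 and only 4 for H3K4me2 (percentile 96.8 after the GC correction). CDH2, the N-cadherin gene, was higher for H3acetyl (1.96 ± 1.66) and lower for H3K27me3 (-1.30 ± 1.02), while FN1 kept its H3acetyl and H3K27me3 calls in 1 of the 4 scaling alternatives each. CDH1 was the only epithelial marker measured and was lower for all 3 active antibodies, although its H3K4me2 call held in 2 of the 4 scaling alternatives, with H3K27me3 at 0.15 ± 0.39 and not called. Of 8 cadherins and catenins, 2 were higher and CDH1 lower for H3acetyl (median 0.41, percentile 72.0, with a sign that depended on the scaling), CDH6 was higher and CDH1 lower for H3K4me2 (0.27, 80.0, again of either sign), CDH2 was higher and CDH1 lower for POL2 (0.25, 73.2), and CDH2 and CDH6 were lower for H3K27me3 (0.073, 54.3). Of 17 genes of the integrin list, which includes CD44, 4 were higher for H3acetyl (CD44 1.35, ITGA1 1.27, ITGA3 1.09 and ITGA4, median 0.65, percentile 99.03), 2 for POL2 (CD44 and ITGA3, median 0.43, percentile 99.05) and ITGA4 for H3K4me2 (0.24, 84.8). The H3acetyl call held in 0 of the 4 scaling alternatives for ITGA1 and in 1 for CD44, the POL2 call of ITGA3 held in 2 (0.72 near the start and not called), and the list stood apart in 9 of 12 alternatives for H3acetyl and in 10 for POL2. The lowest list medians in the 12 alternatives were 0.16 for H3acetyl and 0.24 for POL2. For H3K27me3 ITGA7 was lower and ITGAM higher (median -0.030, with a sign that depended on the scaling, percentile 18.03), and the ITGA7 call held in 0 of the 4 scaling alternatives. ITGB3 was not called (H3acetyl 0.80 ± 0.61).

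The matrix metalloproteinases, proteases that cleave extracellular matrix, were called at few genes. Of 22 measured genes, 4 from a cluster on chromosome 11 were lower for H3K27me3, MMP1 (-1.80), MMP10 (-1.35), MMP13 (-1.27) and MMP3 (-1.13), and none was higher (median 0.025, percentile 55.7). MMP10 and MMP13 kept these calls in 3 of the 4 scaling alternatives. For H3acetyl, MMP10 (1.05) and MMP3 (1.02) were called higher and MMP1 was not (0.71 ± 0.69), MMP3 was higher for H3K4me2 (1.29, list median 0.15, percentile 50.9), and none was called for POL2 (0.17, 86.6). None of these active calls held under any of the 4 scaling alternatives, while with probes within 1000 bp of a start MMP10 was higher for H3acetyl (1.72) and H3K4me2 (2.20), MMP3 for both (1.25 and 1.30) and MMP19 for H3K4me2 (1.45). The H3acetyl median of 0.41 stood apart (percentile 98.5), but loess gave -0.077 (58.1) and the GC correction -0.017 (90.6), so that its sign, like those of the other 3 medians, depended on the scaling. The gelatinases were not called: MMP2 was at -0.39 ± 0.69 for H3K27me3 and 0.76 ± 1.14 for H3acetyl, and MMP9 at 0.88 ± 0.86 and -0.62 ± 0.32, though with probes within 1000 bp of a start MMP9 was higher for H3K27me3 (1.02). The membrane-type genes MMP14 (H3acetyl 0.50 ± 0.79), MMP15 (-0.58 ± 0.55) and MMP24 (-0.15 ± 0.49 over 159 probes) were not called either. Of the 5 inhibitors, TIMP3 alone was called, lower for H3K4me2, and kept that call in 2 of the 4 scaling alternatives. List medians were -0.089 for H3K27me3 (percentile 36.3), -0.12 for H3acetyl (47.9), 0.053 for H3K4me2 (47.5) and -0.026 for POL2 (36.2), and only the sign for H3K27me3 was the same under all scalings. TIMP1 and TIMP2 were at -0.12 ± 0.61 and -0.26 ± 0.61 for H3acetyl.

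Growth factor genes of angiogenesis stood apart for H3acetyl and H3K27me3 in all 12 alternatives and for POL2 in 8. Over the alternatives the list median ranged from 0.30 to 1.01 for H3acetyl, -0.56 to -0.34 for H3K27me3 and 0.20 to 0.42 for POL2. Of 19, 7 were higher for H3acetyl (FGF2 1.91, MET 2.01, TGFB2 1.86 and EGF 1.57 among them, median 0.71, percentile 99.7) and 2 for POL2 (MET 1.24 and TGFB2 1.71, median 0.34, percentile 98.4). For H3K27me3, 3 were lower (IGF1 -1.77, ANGPT1 -1.71 and TGFB2 -1.14) and FLT4 was higher (1.03), with a median of -0.39 (percentile 0.64). The TGFB2 calls for H3K27me3 and H3acetyl and the MET calls for H3acetyl and POL2 held in 3 of the 4 scaling alternatives. Input DNA of TGFB2 and ANGPT1 was lower in U251 (-1.17 and -0.95), which may affect their ratios. For H3K4me2, 6 were higher (FGF1 1.91 and HGF 1.23 among them, median 0.28, percentile 90.03), and HGF kept its call in 2 of the 4 scaling alternatives.

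**Figure D4:**
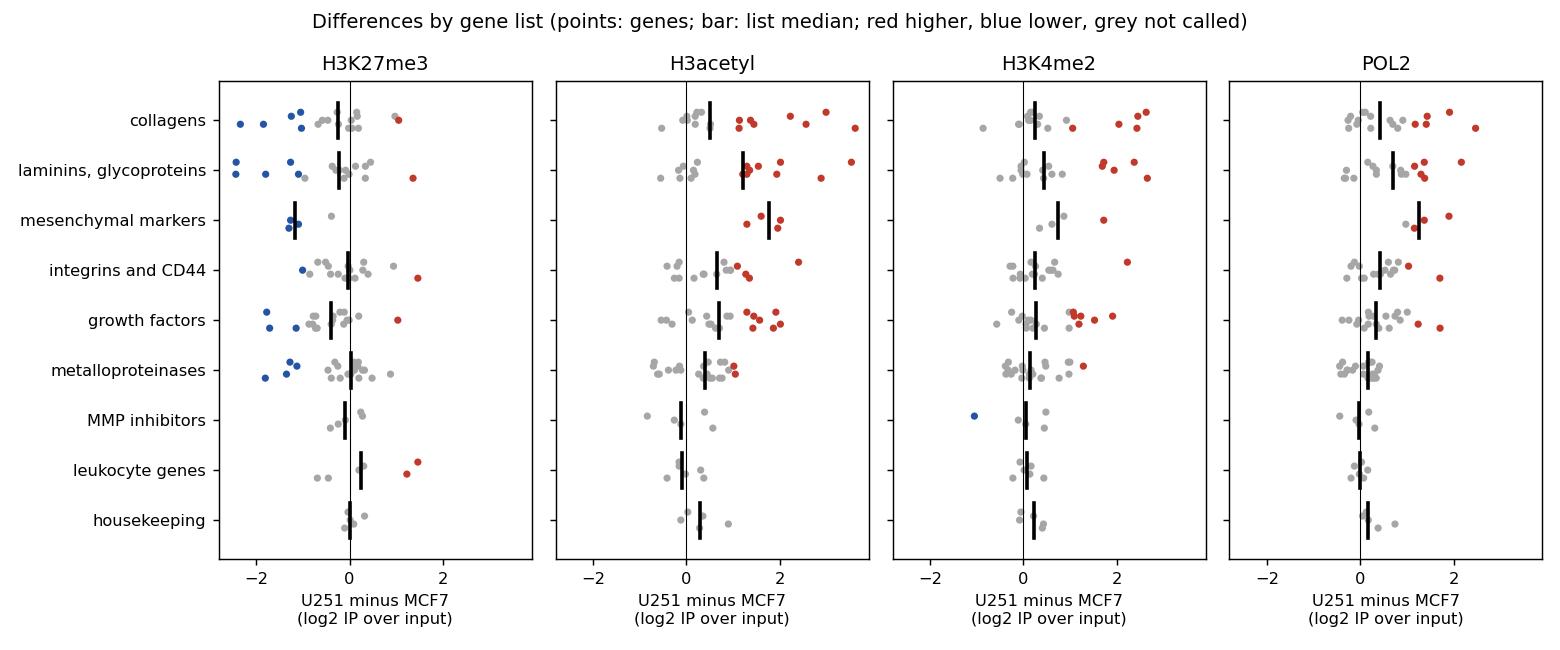
Difference U251 minus MCF7 in log2 IP over input (x axis) of each member (points) of 9 gene lists (y axis), 1 panel per antibody, with a bar at the list median and red, blue and grey for genes called higher, lower or not called. The glycoprotein and mesenchymal lists have H3acetyl medians of 1.21 and 1.78, against 0.28 for housekeeping genes, whose sign depended on the scaling.

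The remaining lists of at least 3 measured genes, leaving aside those chosen after the values were seen, did not stand apart for any antibody. Of 4 plasminogen system genes, PLAU (1.43) was higher for H3acetyl (median 0.49, percentile 81.1) and PLG (1.24) for H3K27me3 (0.12, 56.5). For H3K4me2 (0.46, 81.2) and POL2 (0.57, 97.3) none was called. PLAU, with 3 probes, was at 1.07 for H3K4me2 and 1.49 for POL2, above the size threshold. It missed both calls because only 66.7% of its probes had the same sign. Of 10 cathepsin and furin family genes, CTSS was higher for H3acetyl (1.07) and H3K4me2 (1.37), with list medians of 0.13 for H3K27me3 (percentile 72.7), 0.11 for H3acetyl (53.0), 0.0013 for H3K4me2 (28.5) and 0.053 for POL2 (43.0), the last 3 with a sign that depended on the scaling. The CTSS calls held in 0 (H3acetyl) and 3 (H3K4me2) of the 4 scaling alternatives. The CTSS input was lower in U251 (-1.24), which may affect its ratios. Of 3 ADAMTS genes, ADAMTS13 was higher for H3K27me3 (1.11), with medians of -0.22 (percentile 33.6), -0.26 (21.9), -0.064 (24.4) and -0.16 (14.7) for H3K27me3, H3acetyl, H3K4me2 and POL2. The ADAMTS13 call held in 3 of the 4 scaling alternatives, and near the start its difference was 0.52 and not called. Of 6 blood cell genes, CD8A (1.23) and ITGAM (1.46) were higher for H3K27me3 (median 0.25, percentile 83.7), and none was called for H3acetyl (-0.088, 30.7), H3K4me2 (0.078, 24.9) or POL2 (0.0041, 45.7), whose signs depended on the scaling. Near the start CD8A was at 0.87 and not called. Of 4 developmental polycomb targets, PAX6 was lower for H3K27me3 (-1.30) and higher for H3acetyl (1.16), with medians of -0.49 (12.8), 0.25 (58.0), 0.50 (87.0) and -0.053 (27.8), of which that of H3acetyl changed sign with the scaling. The PAX6 call for H3acetyl held in 0 of the 4 scaling alternatives, and near the start its H3K27me3 difference was -0.84 and not called. Of 11 tumour suppressor and cell cycle genes, APC was higher for H3acetyl (1.32) and H3K4me2 (1.37), with medians of 0.013 (17.9), 0.028 (18.7), 0.16 (58.2) and 0.034 (14.8), the last 3 of either sign depending on the scaling. The APC calls held in 0 (H3acetyl) and 2 (H3K4me2) of the 4 scaling alternatives. Of 13 chromatin modifiers, HDAC9 was called for all 4 antibodies, lower for H3K27me3 (-1.40) and higher for the others, with list medians of 0.029 (34.9), 0.21 (39.2), 0.18 (68.3) and 0.22 (62.4), where only the POL2 sign was the same under all scalings. Lists of fewer than 3 measured genes were not tested. Of 2 neuronal markers, NCAM1 was lower for H3K27me3 (-1.48) and higher for H3acetyl (1.25). The glial markers S100B and SOX2 and the luminal breast marker ERBB2 were not called, with H3acetyl at 0.62, 0.77 and -0.15. None of 5 housekeeping genes was called (medians 0.014, 0.28, 0.22 and 0.17, percentiles 35.9, 56.6, 67.2 and 49.4, all with a sign that depended on the scaling), and ACTB and GAPDH were at 0.28 ± 0.50 and -0.12 ± 0.58 for H3acetyl.

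The input DNA itself differed between the lines at 84 genes, 38 higher and 46 lower in U251, by limma on 4 input channels per line. The largest difference was at PARD6B on chromosome 20 (probes 48779142 to 48783962), at 2.62 ± 0.03 in MCF7 and -0.46 ± 0.13 in U251 (SD, n = 4 each), a difference of -3.08 ± 0.08 (SE, limma adjusted p = 8.07e-11). GJB2, the connexin 26 gene on chromosome 13 (-1.29 ± 0.09, limma adjusted p = 2.32e-06), CTSS, TGFB2 and ARNT on chromosome 1 (-1.24, -1.17 and -1.13), and MMP16, the oncogene MYC and ANGPT1 on chromosome 8 (-1.12, -0.98 and -0.95) were also lower. The 8 largest higher differences were chemokine genes of chromosome 17, CCL13 (1.14 ± 0.10, limma adjusted p = 1.39e-05), CCL23 (1.13), CCL1 (1.11), CCL11 (1.01), CCL14 (1.01), CCL16 (0.99), CCL8 (0.98) and CCL2 (0.95). Of 49 genes on chromosome 17, 20 were higher and 2 lower (median 0.40). The 4 values of a line did not overlap those of the other at 226 of the 534 genes, where chance gives 2.86%. Normexp background correction gave 22 genes higher and 10 lower. Differences of the IP over input values followed the input difference at most weakly across genes. Values were r = 0.082 (rho = 0.0068) for H3K27me3, -0.112 (-0.162) for H3acetyl, -0.080 (-0.104) for H3K4me2 and -0.110 (-0.183) for POL2.

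**Figure D5:**
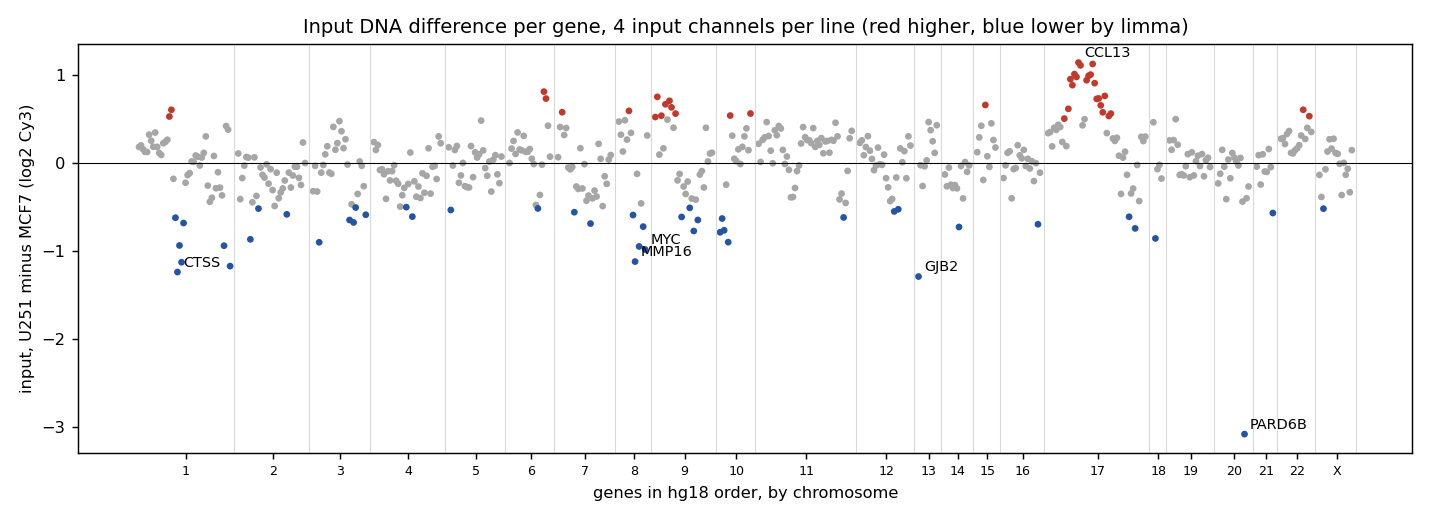
Input difference U251 minus MCF7 in log2 Cy3 intensity (y axis) for genes in hg18 order by chromosome (x axis), 4 input channels per line, with red and blue for genes called higher and lower by limma. PARD6B lies at -3.08, and 20 of the 49 genes of chromosome 17 are higher, with CCL13 at 1.14.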

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

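No comparison of single samples within a group other than the input values could be tested, since each line and antibody had 1 array. For the weighed patterns, the tests were written down before their results were seen, but the GC correction and the chemokine list were chosen after the data had been seen (planned: no). The input level of GJB2 in U251 was -1.196 on the H3K4me2 array and -1.473 to -1.426 on the other 3 arrays, a gap of 0.8313 of the range. This gap exceeded the 95% critical value of Dixon's test, which chance exceeds in about 1 of 20 of the 32 groups tested.

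The excess of genes with higher H3acetyl in U251 may be a difference between the lines, between the 2 hybridizations or between slide columns, which the design cannot separate. A GC trend may account for part of it, since the correction lowered the higher calls from 74 to 40 and moved the median of all genes from 0.17 to -0.10, but not for all, since 80% of called genes were still higher (bootstrap interval 67.9% to 90.4%). A wider spread on the U251 array does not account for it alone either, since 72.22% were higher after quantile normalization (62.1% to 82.3%), compared with 89.2% in the main values. Normexp background correction gave 20 higher and 23 lower genes, so that the treatment of background could produce much of the excess. TNC, COL11A1 and SGCE, the largest H3acetyl differences, were called higher in all 4 scaling alternatives, as were others such as COL4A2 and HDAC9. Their lowest values there were 2.16 at TNC, 1.98 at COL11A1 and 1.54 at SGCE, which has 4 probes. Rescaling the same arrays cannot separate the lines from the hybridizations or the slide columns.

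The higher H3K27me3 in U251 at chemokine and chemokine receptor genes may reflect Polycomb repression of immune genes in that line. The active antibodies showed no general loss at these 44 genes. For H3acetyl 6 were higher and 1 lower (median 0.098), for H3K4me2 4 and 0 (0.20), and for POL2 1 and 0 (0.049). The signs of these medians depended on the scaling. The blood cell list, fixed in advance, did not stand apart for H3K27me3 (percentile 83.7). Input DNA of the chromosome 17 cluster was higher in U251, and the H3K27me3 median was also larger on that chromosome (0.80). Outside chromosome 17 the list median was 0.3713, above the random range of -0.29 to 0.24 but below the 0.5 set in advance. The pattern was thus not confined to chromosome 17, but the test as set in advance did not decide on the input difference. With the input difference removed, a test chosen after this result was seen, the whole list stayed at 0.73. That removal could change little, since H3K27me3 differences hardly followed the input difference over all genes (r = 0.082). It therefore does not decide on the input difference either. A GC trend does not account for the pattern, since the list median was 0.7412 after the GC correction (random range -0.27 to 0.25). Random lists drew genes singly, so neighbouring genes of a cluster that change together would make both random ranges too narrow. With 1 H3K27me3 array per line, a biological cause was not tested.

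The difference in input DNA may reflect gains and losses of chromosome segments that set the 2 lines apart. Differences of neighbouring genes within 5 Mb correlated at 0.6881 over 358 pairs, above the highest of 1000 shufflings (0.169), as segment changes need. Noise between hybridizations does not account for it, since only 1 of the 35 splits into 4 and 4 channels, the real one, called as many genes (highest other 0), but if the 4 inputs of a line were 1 DNA preparation, the splits say nothing on differences between preparations. A GC trend does not account for it either, since 82.14% of the called genes were called with the same sign after the GC correction. Slide column stayed confounded with the line, and no copy number data were used here.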

How the results depend on the processing

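Results were recomputed under the alternatives that apply to them, and 85 of the values that answer a comparison moved beyond their spread, 2 that stood apart changed sign and 1205 stayed within their spread or within 1.5 times a count. Medians of lists that did not stand apart also changed sign, as given with each list. The GC correction, the 1000 bp limit and the removal of the input difference were chosen after seeing the data (planned: no). No paired analysis was possible by replicate because the labels give no replicate numbers and each line and antibody had 1 array, and for the input the antibody as a block left the counts at 38 and 46. The use of the deposited value table was not run, since its values match no probe column, and the slide as a block was not run, since there was 1 slide. The cause of the shifts was not tested. Of 131 named calls, normexp ended 29, loess 23, the GC correction 23, the 1000 bp limit 17, quantile normalization 14 and even-ranked probes 14. With the 1000 bp limit only 458 genes had at least 3 probes. Calls of named genes without a value there, such as SGCE, COL4A1, COL4A2, NRG1, CDH2 and PLAU, could not be checked and are not among the 17. Even-ranked probes gave 265 of the 285 named values. The 17 calls that ended with the 1000 bp limit were those of ADAMTS13, CD8A, ITGA7, LECT1, PAX6 and TGFB2 for H3K27me3, TGFB2 for H3acetyl, APC, MIF, TIMP3 and VCAM1 for H3K4me2, and CCL2, IL17C, ITGA3, MIF, SPP1 and TGFB2 for POL2. Differences of at least 1 remained at TGFB2 (-1.20, 1.56 and 1.27 for H3K27me3, H3acetyl and POL2), VCAM1 (2.59) and CCL2 (1.49), which failed the rule on the sign of the probes instead. Named calls that ended in at least 1 of the 4 scaling alternatives were ADAMTS13, COL11A1, COL4A1, COL4A2, FN1, ITGA7, MMP10, MMP13 and TGFB2 for H3K27me3, and APC, CD44, CDH2, CTSS, FN1, IL10RA, ITGA1, MET, MMP10, MMP3, PAX6, PLAU, SHH, TGFB2 and TGFBI for H3acetyl. For H3K4me2 they were APC, CDH1, CTSS, EGF, HGF, MMP3, NRG1, SGCE and TIMP3, and for POL2 ASCL2, CDH2, IL17C, ITGA3, MET, MIF and PTN. Leave-one-out of the input channels gave 37 to 45 genes higher and 39 to 49 lower.

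With normexp, 30 genes were lower for H3K27me3 (main 49), 20 higher and 23 lower for H3acetyl (74 and 9), 2 lower for POL2 (4) and 12 lost H3K27me3 with a gain of an active mark (37). Input DNA was higher at 22 genes and lower at 10 (38 and 46). The level correlation of H3K27me3 with H3acetyl in U251 was -0.533. Correlations of differences were -0.302 for H3K27me3 with H3acetyl, 0.673 for H3acetyl with H3K4me2 and 0.6498 for H3acetyl with POL2. H3acetyl list medians were 0.96 for mesenchymal markers, 0.24 for blood cell markers and -0.17 for housekeeping genes.

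With loess, 27 genes were higher for H3K4me2 (49), 2 lower for POL2 and 20 lost H3K27me3 with a gain of an active mark. Level correlations of H3K27me3 in U251 were -0.544 with H3acetyl and -0.527 with POL2. The H3acetyl median of the metalloproteinases changed sign to -0.077, and the H3K4me2 median of chemokines on chromosome 17 was -0.56. Quantile normalization gave 20 genes lower for H3acetyl and 18 for H3K4me2 (10). It gave medians of 1.44 for mesenchymal markers (H3acetyl), -0.18 for blood cell markers (H3K4me2), and -0.13 (H3acetyl) and -0.11 (POL2) for housekeeping genes.

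The GC correction called 40 genes higher for H3acetyl, 31 higher for H3K4me2 and 2 lower for POL2. Correlations of differences were 0.803 for H3acetyl with H3K4me2, 0.878 for H3acetyl with POL2 and 0.637 for H3K4me2 with POL2. The metalloproteinase median for H3acetyl changed sign to -0.017, and the housekeeping median for H3K4me2 was -0.025. Main and GC-corrected splits of higher against lower genes were 74 to 9 and 40 to 10 for H3acetyl and 49 to 10 and 31 to 15 for H3K4me2.

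The 3 highest probes gave 21 genes lower for H3acetyl, 21 lower for H3K4me2, 64 higher and 8 lower for POL2, and 5 that gained H3K27me3 and lost an active mark (2). Level correlations of H3K27me3 with H3acetyl, H3K4me2 and POL2 were -0.263, -0.00213 and -0.259 in MCF7 and -0.482, -0.377 and -0.431 in U251. Correlations of differences were 0.780 for H3acetyl with H3K4me2, 0.857 for H3acetyl with POL2 and 0.598 for H3K4me2 with POL2. Medians were 0.53 (H3acetyl) and 0.31 (POL2) for metalloproteinase inhibitors, 1.81 for mesenchymal markers (POL2), and -0.22 (H3K4me2) and -0.19 (POL2) for blood cell markers. Even-ranked probes gave 1.44 for mesenchymal markers (H3acetyl), and the median over probes gave 0 genes lower for POL2 and 1 that gained H3K27me3 and lost an active mark.

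Probes within 1000 bp of a start gave 29 of 458 genes higher for H3K27me3 (45 of 534). Level correlations of H3K27me3 were -0.324 with H3acetyl, -0.0343 with H3K4me2 and -0.305 with POL2 in MCF7, and -0.553 with H3acetyl and -0.508 with POL2 in U251. The differences of H3K4me2 and POL2 correlated at 0.640, and the mesenchymal median for H3acetyl was 1.39 and no longer stood apart (percentile 92.6).

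A size threshold of 0.5 called 86 genes higher and 92 lower for H3K27me3, 143 and 47 for H3acetyl, 112 and 37 for H3K4me2, and 91 and 21 for POL2, with 71 that lost and 15 that gained H3K27me3 against an active mark. A threshold of 1.5 called 12 and 17, 37 and 5, 29 and 3, and 12 and 0, in the same order, with 9 that lost and 1 that gained it. Without a minimum difference the input was higher at 134 genes and lower at 119.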

Other observations

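Chemokine and interleukin genes, lists chosen after their values were seen, divided in their H3K27me3. Of 44 chemokines and chemokine receptors, 14 were higher in U251, among them CCL3 (1.53 ± 0.43), CCL4 (1.46 ± 0.35), CCL18 (1.34 ± 0.49), CCR6 (1.32 ± 0.37) and XCR1 (1.49 ± 0.88), 7 were lower and 23 were not called (median 0.69). The lower genes were CXCL1 (-1.57 ± 0.86), CXCL2 (-1.15 ± 0.80), CXCL3 (-1.31 ± 0.74), CXCL5 (-1.33 ± 0.69) and IL8 (-1.08 ± 0.71), which encode neutrophil attractants, the monocyte attractant CCL2 (-1.19 ± 0.88) and the receptor CXCR4 (-1.27 ± 0.54). CXCL2, CXCL3 and IL8 were also higher for H3acetyl (1.11, 1.61 and 1.60). Of 23 interleukin genes, 5 of the interleukin 1 family were higher for H3K27me3, IL1F10 (1.52 ± 0.47), IL1F5 (1.15 ± 0.83), IL1F6 (1.10 ± 0.21), IL1RN (1.08 ± 0.57) and IL1F9 (1.03 ± 0.66), and IL6 was lower (-1.60 ± 0.77), with a median of 0.38. These medians kept their sign under every scaling, the lowest being 0.50 for the chemokines and 0.35 for the interleukins, and the interleukin median was 0.21 with probes within 1000 bp of a start. Genes were counted singly, also where they are neighbours in a cluster and may report a single region.

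The cell cycle inhibitor gene CDKN2A, chosen after its values were seen, lost 7 of its 10 probes to the probe filter, and 6 of them were dim on all 4 arrays of each line. PARD6B, which had the highest H3acetyl and H3K4me2 means in MCF7 (2.58 and 2.16), also had an input of 2.62 there, so that the marks were high relative to an input that was itself high. In U251 the input of PARD6B was -0.46.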
